A study of Mus musculus with 8 samples.

How the data were processed

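RNA from sorted mouse T cells was measured on 8 microarrays, 4 from animals given an isotype control antibody and 4 from animals given an antibody that blocks the receptor for interleukin 10 (IL-10R). Per the labels' protocols, female C57BL/6 mice received leukaemia cells of the Eµ-TCL1 line, a mouse model of chronic lymphocytic leukaemia (CLL) in which a transgene drives a B cell leukaemia. Treatment began 3 weeks after transplantation, lasted 2 weeks per the series text, and the spleens were taken 5 weeks after transplantation. The labels disagree on the dosing interval, and no dosing interval is used here. The sorted population was negative for a lineage cocktail, positive for the T cell receptor beta chain and CD8, low for CD127, intermediate to high for CD44 and high for PD-1. RNA was extracted with a column kit for small samples, labelled by the WT Pico procedure and hybridised to GeneChip Mouse Gene 2.0 ST arrays, with 1 labelled sample per array, per the labels' protocols.

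The deposited values are on a log2 scale with 1 value per transcript cluster and array, which was read from their range, 1.57 to 13.89. The authors made them with Affymetrix Power Tools, per the submitters' processing notes; its version, the summarisation algorithm and the normalization between arrays are not given in the sources used here. The array medians over all rows lay between 5.19 and 5.31. No 2 arrays held identical values. Scanner files were not used here, so detection above background could not be set per probe. The level of a gene cannot be compared with that of another gene, because each transcript cluster has its own probes, and the number of arrays limits the precision of every difference.

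The table holds 41345 rows. Gene names came from an annotation of the array platform, with symbols checked through gene identifiers against the RefSeq genes of GRCm38.p6. Exactly 1 gene symbol was found for 23521 rows, several symbols for 1814 rows, and 16010 rows had no entry in that annotation and are unnamed here. The rows with 1 symbol covered 22180 genes. Of several rows of a gene (1082 genes), the row with the highest mean over the 8 arrays was kept. Genes entered the tests if their mean over all 8 arrays was at least 5.24, the median of the row means, which left 12019 genes. Genome positions are not given, since the build behind the array annotation is not named. The rows of a gene differed in sign for 4 of the 19 genes past the threshold that had several rows (A230006K03Rik, Adam19, Itpr3 and Zkscan7).

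Differences are anti-IL-10R minus isotype on the log2 scale, with the standard error (SE) of limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, total degrees of freedom 9.59). P-values are two-sided with Benjamini-Hochberg adjustment, and the threshold was an adjusted p below 0.05. The labels do not state that each array came from a separate animal, so the p-values measure the spread between these arrays. The 17 gene lists described in the report were compared with all other tested genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists. Beside it stand camera with a correlation estimated for each list, fry, and the members past the threshold adjusted over all tested genes and adjusted over the list alone. Of 10 marker lists for other cell types, 9 had at least 5 members and were tested in the same way without the filter on dim genes; the list for gamma delta T cells was too short. The preset value suits weakly correlated genes, whereas the estimated correlation and fry take account of members that vary together.

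The genes named were set by a rule. It took the 12 genes with the highest and the 12 with the lowest change among those past the threshold whose groups did not overlap, leaving predicted, Rik, microRNA and snoRNA genes unnamed. It also took the genes of the sort and of the treatment target, and up to 4 members with the smallest p in each list. This rule, the lists, the tests and the alternatives were fixed before the data were examined, except where a test or list is said to have been chosen later. A rule for matching older gene symbols to list members was corrected after a first run had matched 4 list symbols to other genes, and every result is from the corrected matching. The alternatives were no filter and a stricter filter (means of at least 6.97) on dim genes, quantile normalization, centring of each array and the mean of all rows of a gene. They were also a trended and robust variance model, array weights (limma with statmod 1.5.0), the replicate number as a block, the B cell marker mean as a covariate, each array left out in turn, other thresholds, all rows of the table and an unmoderated Welch test.

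The pipeline was tested on simulated data with the spread of the 12019 tested genes in the comparison of anti-IL-10R with isotype, in which 200 genes were changed. It called 68% of the genes changed 2-fold and 97% of those changed 4-fold, and 4.07% of its 172 calls were unchanged genes. None (0) of 10 lists of unchanged genes passed the threshold. The simulated genes varied independently of one another, and no simulated array stood apart. The simulation therefore gives no error rate for lists whose members vary together.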

Results

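PD-1hi effector CD8 T cells, a population that carries high amounts of the inhibitory receptor PD-1 on its surface, were sorted from the spleens of leukaemia-bearing mice, and their gene expression was measured on 8 arrays. The cells of 4 samples came from mice given an isotype control antibody and those of the other 4 from mice given an antibody against the IL-10 receptor. The comparison asks what blocking the IL-10 receptor changed in the transcriptome of these T cells in the presence of a B cell leukaemia. The arrays had similar overall levels, with medians of 5.19 to 5.31 on the log2 scale over all 41345 rows. Over the 12019 tested genes, isotype replicate 1 correlated less with the other arrays (Pearson's r across genes, which are not independent replicates, 0.915 to 0.929) than the other 7 did with one another (0.962 to 0.986). The first principal component, with 46.7% of the variance, set that array apart, and the second, with 22.8%, parted the 3 other isotype arrays from the 4 anti-IL-10R arrays. Counts of changed genes are therefore given with and without isotype replicate 1.

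**Figure D1:**
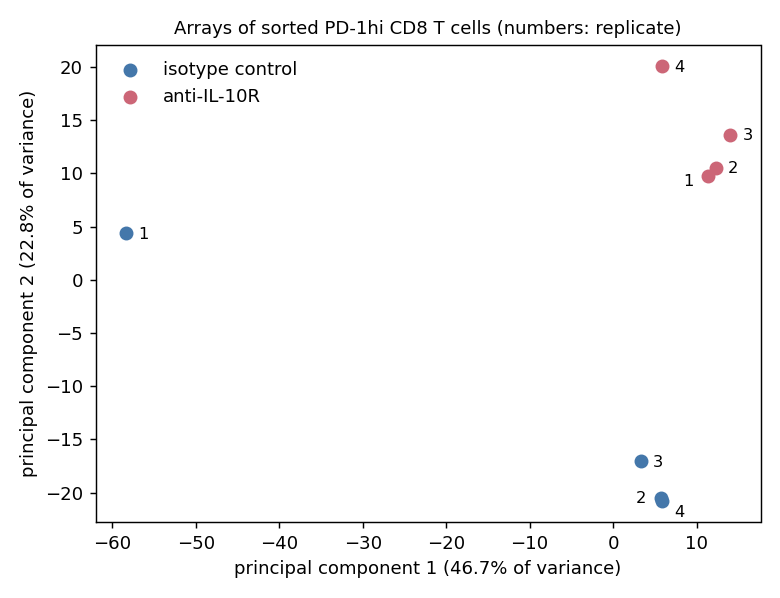
Principal components 1 and 2 of the 8 arrays over the 12019 tested genes, in component units of the log2 values, with isotype arrays in blue, anti-IL-10R arrays in red and replicate numbers beside the points. Isotype replicate 1 lies at −58.3 on component 1 and 4.35 on component 2, while isotype replicates 2 to 4 lie between −20.7 and −17.1 on component 2 and the anti-IL-10R arrays between 9.78 and 20.04.

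Among the genes of the sort, Cd3e, Cd8a, Cd8b1 and Pdcd1 had high signals in both groups. Cd44 had lower ones, 6.44 ± 0.26 (SD, n = 4) in the isotype group and 6.63 ± 0.20 in the anti-IL-10R group. Cd3e, a chain of the T cell receptor complex, had a mean of 12.33 ± 0.10 (SD, n = 4) in the isotype group and 12.60 ± 0.02 in the anti-IL-10R group. The CD8 chains Cd8a and Cd8b1 differed by 0.31 ± 0.09 (SE) and 0.30 ± 0.11. Pdcd1, which encodes PD-1, differed by 0.50 ± 0.19, with 10.95 ± 0.40 (SD) in the isotype and 11.45 ± 0.09 in the anti-IL-10R arrays. Without isotype replicate 1 (10.34, against 11.10 to 11.20 in the other isotype arrays) its difference was 0.30. Il7r, which encodes the CD127 chain used to exclude cells, was dim, with 3.57 ± 0.62 and 3.60 ± 0.50. Of the genes of the treatment target, Il10ra, the ligand-binding chain of the receptor, differed by 0.51 ± 0.13 and was higher in all 4 anti-IL-10R arrays than in any isotype array. The same separation held for the sort genes Cd3e, Cd8a, Cd8b1 and Pdcd1, so it was not particular to Il10ra. The groups overlapped for Cd44, Il7r and Il10rb. Il10rb differed by 0.07 ± 0.14 (0.01 without isotype replicate 1 or anti-IL-10R replicate 1, and 0.18 without anti-IL-10R replicate 4). Il10 itself differed by 0.76 ± 0.29 with overlapping groups, and by 0.48 without anti-IL-10R replicate 2. None of these genes, nor Cd44, passed the threshold over all 22180 genes without a filter (limma adjusted p 0.0977 for Il10ra, 0.174 for Cd8a, 0.255 for Pdcd1, 0.256 for Il10 and Cd3e, 0.276 for Cd8b1, 0.632 for Cd44, 0.868 for Il10rb and 0.976 for Il7r). Over the filtered genes, the adjusted p of Il10ra was 0.0648, and 0.0413 without isotype replicate 1. The constant chains of the T cell receptor (Trac, Trbc1 and Trbc2) were not analysed here.

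After IL-10R blockade, 148 genes were higher and 156 lower among the 12019 tested. The genes that rose most included Slco2a1, a prostaglandin transporter, Mxd4, a partner of MAX that opposes MYC, the transcription factor Maf, and 2 receptors of the CD200 receptor family. Those that fell most included histone genes, the chemokine gene Xcl1 and genes of DNA replication and mitosis. Changes past the threshold ranged in size from 0.42 to 2.73 on the log2 scale, and 24 of the higher and 28 of the lower genes changed at least 2-fold. All 304 had groups that did not overlap; of all tested genes 15.3% did so, where chance gives 2.86%. Without isotype replicate 1 the same fit called 403 genes higher and 709 lower, and all 304 genes were kept among these 1112; after quantile normalization of all arrays it called 204 higher and 427 lower. The count was 48 without isotype replicate 2, 50 without isotype replicate 3, 3 without isotype replicate 4, and 62, 10, 8 and 12 without anti-IL-10R replicates 1, 2, 3 and 4. All 304 genes kept their direction in each of these fits. With 1 array left out this was fixed in advance, since their groups did not overlap.

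Among the genes that rose, Slco2a1 (transcript cluster 17520905) went from 6.99 ± 0.45 (SD, n = 4) to 9.42 ± 0.07, a 5.38-fold change (95% CI 3.93 to 7.36, limma adjusted p = 0.00173). Mxd4 rose from 7.88 ± 0.11 to 9.39 ± 0.16, which is 2.84-fold (95% CI 2.36 to 3.41, adjusted p = 0.00147). Cd200r2 differed by 2.73 ± 0.59 (SE), with a wide spread among the anti-IL-10R arrays (SD 1.32, adjusted p = 0.0471). Cd200r1, the inhibitory receptor for CD200, rose by 1.33 ± 0.18 (adjusted p = 0.017). Cd200r4, chosen after its value was seen, rose by 1.13 ± 0.20; these paralogs are similar in sequence, so their probes may not measure them separately. Klk1b27 rose by 2.53 ± 0.39, with the same limit, since the kallikrein 1 genes are near-identical copies. Cd200r2, Klk1b27 and Plekhg1 had isotype means of 4.98, 4.81 and 4.93, below the limit for dim genes, so the sizes of their differences are uncertain. Plekhg1, Lrrc9 and the cell adhesion gene Dscam rose by 1.54 ± 0.30, 1.48 ± 0.22 and 1.47 ± 0.17. Maf, a transcription factor that drives Il10 transcription in T cells, and Mrc2, a collagen receptor, both rose by 1.45, with SEs of 0.30 and 0.19. Spo11, known for cutting DNA in meiosis, rose by 1.39 ± 0.18, and Car2, a carbonic anhydrase, and Trp53inp1, a p53-induced gene, both rose by 1.36, with SEs of 0.23 and 0.28.

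Among the genes that fell, H1f1, a linker histone, fell by 2.12 ± 0.13 (SE), from 7.27 ± 0.16 (SD, n = 4) to 5.15 ± 0.19 (limma adjusted p = 0.000346, the smallest of all genes). Xcl1, a chemokine that attracts cross-presenting dendritic cells, went from 10.06 ± 0.24 to 8.15 ± 0.48, a difference of −1.91 ± 0.23 (adjusted p = 0.017). The core histone genes H2bc12, H2bc18 and H2ac21 fell by 1.56 ± 0.33, 1.30 ± 0.23 and 1.16 ± 0.21; histone genes are near-identical copies, so the values of single members are uncertain. Gpr18, a G protein-coupled receptor, fell by 1.57 ± 0.19, Bex2 by 1.37 ± 0.30 and Emb, a membrane glycoprotein, by 1.30 ± 0.21. The anti-IL-10R means of H1f1 and Bex2 (4.94) lay below the limit for dim genes, so the sizes of their differences are uncertain too. Cdca7, a target of MYC and E2F, fell by 1.29 ± 0.17. Lrr1, which acts in unloading the replication machinery, fell by 1.28 ± 0.24, and Fam83d, a spindle protein, fell by 1.15 ± 0.17. Fabp5, a fatty acid binding protein, went from 10.97 ± 0.16 to 9.83 ± 0.14, a difference of −1.14 ± 0.12 (adjusted p = 0.011).

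**Figure D2:**
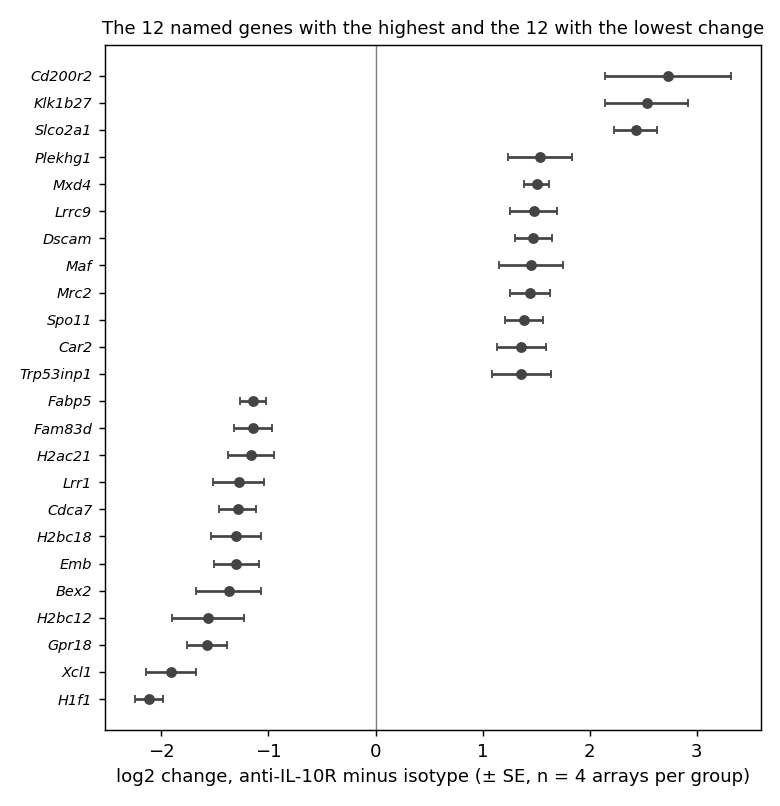
Log2 change (anti-IL-10R minus isotype, horizontal axis) of the 12 named genes with the highest and the 12 with the lowest change, with limma's SE as bars and 4 arrays in each group. The changes run from −2.12 for H1f1 to 2.73 for Cd200r2.

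Cell cycle genes were lower with camera's preset correlation (adjusted p 3.61e-26), but the list lost its call with an estimated correlation (adjusted p = 0.40). All 38 measured members of the list were lower after IL-10R blockade, with a median change of −0.63. Of them, 15 passed the threshold over all genes, 34 when adjusted over the list alone, and 34 over all genes without isotype replicate 1. Plk1, a kinase of mitotic entry, went from 10.76 ± 0.11 (SD, n = 4) to 9.91 ± 0.13, a difference of −0.84 ± 0.11 (SE, limma adjusted p = 0.017). Ccne1, the cyclin of S phase entry, fell by 0.71 ± 0.11, Rrm2, a subunit of ribonucleotide reductase, by 0.86 ± 0.15, and Nusap1, a spindle protein, by 0.65 ± 0.12. Per array, the list mean was 9.16 to 9.65 in the isotype group and 8.76 to 9.05 in the anti-IL-10R group, and isotype replicate 1 was the lowest of its group. The correlation between members was estimated at 0.58, against the preset 0.01. By fry, which does not compare with other genes, the adjusted p was 0.0217.

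The inhibitory receptor and exhaustion list was higher with camera's preset correlation (adjusted p 7.56e-08), but lost its call with an estimated correlation (adjusted p = 0.40). By fry the adjusted p was 0.0217. Of its 25 measured members, 23 were higher, with a median change of 0.41. Of them, 4 passed the threshold over all genes, 15 rose when adjusted over the list alone, and 9 passed over all genes without isotype replicate 1. The 4 were Cd200r1, Maf, Entpd1, which encodes the ectoenzyme CD39 (0.55 ± 0.11 SE, limma adjusted p = 0.0371), and Cxcr6, a chemokine receptor of tissue-resident T cells (0.61 ± 0.13, adjusted p = 0.0461). Among other inhibitory receptors, Havcr2, which encodes TIM-3, differed by 0.65 ± 0.18 and Ctla4 by 0.57 ± 0.22. Lag3 and Tigit differed by 0.11 ± 0.10 (0.06 without anti-IL-10R replicate 3) and 0.23 ± 0.10. The 2 members that were lower, Cd160 and Btla, are inhibitory receptors as well and differed by −0.28 ± 0.16 and −0.28 ± 0.18 (both −0.16, without isotype replicate 2 and without isotype replicate 3). These 6 did not pass over all genes and were chosen after their values were seen. Isotype replicate 1 had the lowest list mean, 8.90, against 9.29 to 9.36 in the 3 other isotype arrays and 9.63 to 9.77 in the anti-IL-10R arrays.

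Interferon-linked lists and the IL-10 receptor list were higher by smaller amounts. The interferon gamma response and MHC class I list had a median change of 0.25 with 21 of 24 members higher (camera adjusted p 0.000809 with the preset correlation, adjusted p = 0.48 with an estimated correlation). Without isotype replicate 1 its median was 0.16. In it, 1 member passed over all genes and 3 over the list alone. That member was Nlrc5, the transactivator of MHC class I genes, which rose by 0.56 ± 0.10 (SE, limma adjusted p = 0.03). Gbp4, Irf1 and H2-T23 differed by 0.50 ± 0.14, 0.45 ± 0.12 and 0.39 ± 0.13, and the first 2 passed over the list alone. The type I interferon response list had a median change of 0.24 with 20 of 26 members higher (camera adjusted p 0.0245, adjusted p = 0.48 with an estimated correlation). Its member Trim30a rose by 0.76 ± 0.12 (adjusted p = 0.0227), 2 members passed over the list alone, and Samd9l, Rtp4 and Isg20 differed by 0.42 ± 0.10, 0.63 ± 0.19 and 0.44 ± 0.14. Ddx58, the RNA sensor RIG-I, rose by 0.71 ± 0.13; it was listed under a newer symbol that the gene table does not hold, so it was not counted, and it was chosen after its value was seen. The IL-10 receptor and STAT3 signalling list had a median change of 0.15 with 14 of 19 members higher (camera adjusted p 0.0278, adjusted p = 0.48 with an estimated correlation). Maf alone passed over all genes and 3 members over the list alone. Il6st, the shared receptor chain gp130, and Jak1 differed by 0.73 ± 0.18 and 0.29 ± 0.10. The camera call of the type I interferon list ended without isotype replicate 2 (adjusted p 0.0606), without anti-IL-10R replicate 1 (0.108) and with the B cell marker mean of each array as a covariate (0.175, median 0.10). That of the IL-10 receptor list ended without isotype replicate 2 (0.0606, median 0.23), without anti-IL-10R replicate 2 (0.0959) and with that covariate (0.0912, median 0.02).

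Lists of metabolism and protein production were lower with camera's preset correlation only. It gave adjusted p 0.000421 for glycolysis, 0.000475 for oxidative phosphorylation and 0.00838 for both heat shock and ribosomal proteins, and with an estimated correlation the adjusted p was 0.48, 0.56, 0.48 and 0.56. By fry none of the 4 passed (adjusted p 0.0882 for glycolysis, 0.199 for oxidative phosphorylation, 0.0806 for heat shock and 0.206 for ribosomal proteins). The glycolysis list had a median change of −0.17 with 16 of 18 members lower. Its member Pgam1, phosphoglycerate mutase, fell by 0.59 ± 0.12 (SE, limma adjusted p = 0.0451). There were 5 members past the threshold over the list alone and 6 over all genes without isotype replicate 1. Slc16a3, a lactate exporter, Pfkl and Pgk1 differed by −0.60 ± 0.15, −0.55 ± 0.16 and −0.48 ± 0.14 and passed over the list alone. The oxidative phosphorylation list had a median change of −0.13 with 28 of 34 members lower, and the ribosomal protein list one of −0.10 with 23 of 26 lower. No member of either passed over all genes or over the list alone (Cox6a1 −0.36 ± 0.10, Cox5b −0.31 ± 0.11, Uqcrfs1 −0.34 ± 0.12 and Ndufa9 −0.34 ± 0.13; Rpsa −0.35 ± 0.11, Rps18 −0.31 ± 0.13, Rpl32 −0.31 ± 0.16, or −0.16 without isotype replicate 2, and Rpl8 −0.20 ± 0.10). In the heat shock list, 11 of 12 members were lower with a median of −0.12, and 3 passed over the list alone. The chaperonin pair Hspd1 and Hspe1 differed by −0.50 ± 0.14 and −0.47 ± 0.14, Hsp90aa1 by −0.47 ± 0.15 and Hsph1 by −0.41 ± 0.15. Isotype replicate 1 lay below the lowest anti-IL-10R array in the means of glycolysis (8.15 against 8.17), oxidative phosphorylation (9.26 against 9.31) and ribosomal proteins (9.51 against 9.56). Without it the medians were −0.26 for glycolysis, −0.22 for oxidative phosphorylation, −0.16 for ribosomal proteins and −0.30 for heat shock. Without anti-IL-10R replicate 1 that of heat shock was −0.22. Without isotype replicate 2 the medians of oxidative phosphorylation and ribosomal proteins were −0.07 and −0.04, and the ribosomal protein call ended (camera adjusted p 0.117).

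**Figure D3:**
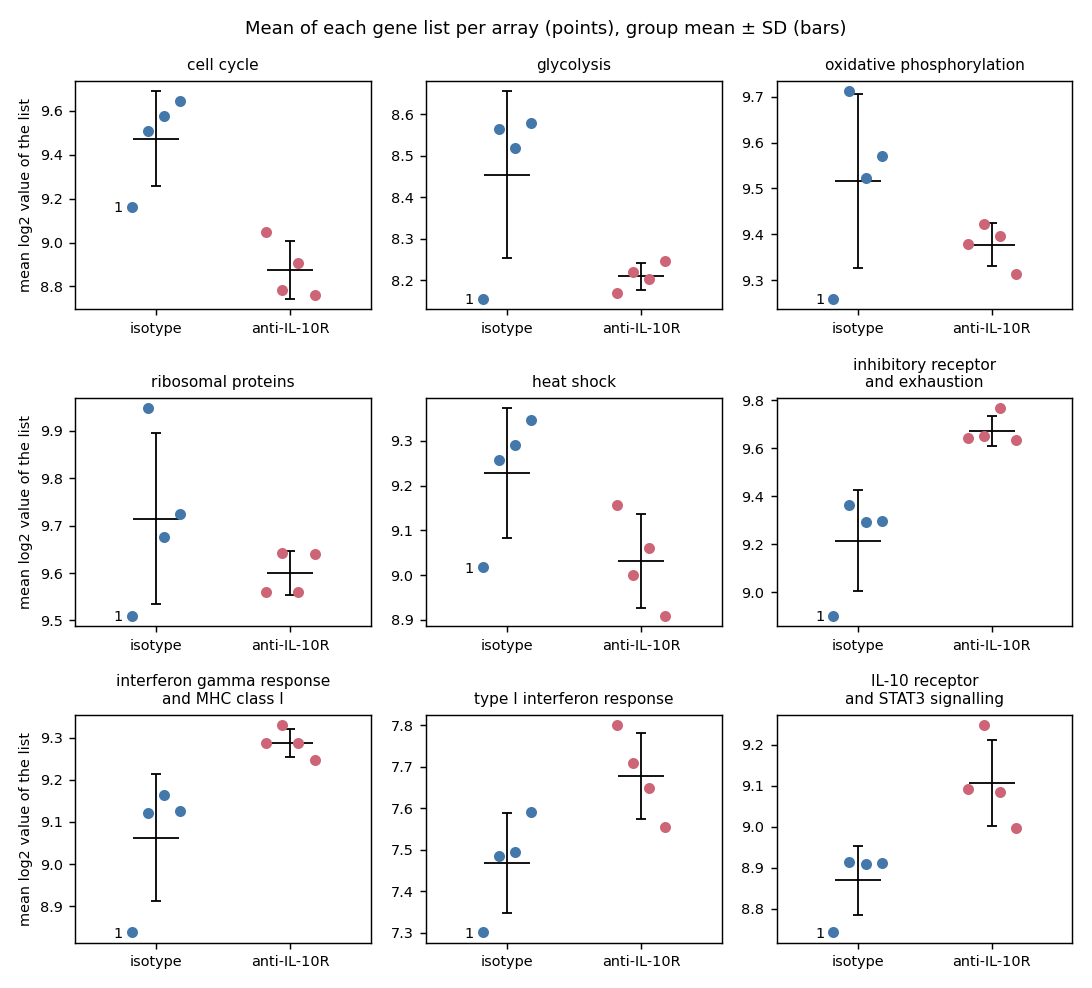
Mean log2 value per array (vertical axis, with its own range in each panel) of the 9 gene lists past the camera threshold with the preset correlation. Isotype arrays are in blue, anti-IL-10R arrays in red, and the group mean ± SD in black. The digit 1 marks isotype replicate 1, which has the lowest isotype value in all 9 panels. For cell cycle, all 4 anti-IL-10R arrays (8.76 to 9.05) lie below all 4 isotype arrays (9.16 to 9.65).

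The other 8 lists did not pass camera's threshold. With 1 array left out, 6 of their medians moved by over 1.5 times. They spanned 0.005 to 0.13 for cytotoxic effector, 0.04 to 0.15 for IL-2 and STAT5 and 0.04 to 0.19 for apoptosis genes. The span was −0.13 to 0.001 for progenitor and memory-like genes, above 0 without isotype replicate 3. Immediate-early genes spanned −0.002 to 0.13, below 0 without anti-IL-10R replicate 3. Cholesterol and fatty acid genes spanned −0.19 to 0.07, below 0 without isotype replicates 1 and 3 and without anti-IL-10R replicates 1, 2 and 3. In the cytotoxic effector list, which holds granzymes, perforin and killer cell receptors, the median change was 0.10 over 24 members (camera adjusted p 0.271). No member passed over all genes, and Fasl and Id2 rose over the list alone, by 0.40 ± 0.09 (SE) and 0.41 ± 0.10. Runx3 and Klrg1 differed by 0.29 ± 0.11 and 0.38 ± 0.16. In the progenitor and memory-like list the median was −0.04 over 16 members (0.171). Over all genes 2 members fell, Xcl1 and Lef1, a transcription factor of naive and memory T cells (−0.98 ± 0.17, limma adjusted p = 0.0291). Il18r1 and Ly6c2 differed by −1.02 ± 0.25 and −1.15 ± 0.34, and over the list alone 4 members fell and 1, Cd27, rose. In the IL-2 and STAT5 list the median was 0.09 over 17 members (0.858). Myc and Xbp1 differed by −0.59 ± 0.16 and −0.42 ± 0.12, and Ikzf4 and Cish by 0.62 ± 0.19 and 0.63 ± 0.19. These 4 passed over the list alone. The costimulatory list had a median of 0.30 over 14 members (0.155), with Slamf1 at 1.02 ± 0.23, Tnfrsf1b at 0.55 ± 0.14, Cd27 at 0.40 ± 0.13 and Cd2 at −0.34 ± 0.10. The list of chemokines, chemokine receptors and integrins had a median of 0.13 over 22 members (0.26), with Xcl1 lower and Cxcr6 higher over all genes and Itga4 and Cxcr3 at 0.37 ± 0.10 and 0.76 ± 0.25.

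Immediate-early genes, which respond within minutes to stimulation or to handling, had a median change of 0.05 over 26 members (camera adjusted p 0.566). Nr4a2, Dusp1 and Ier3 differed by 0.51 ± 0.12 (SE), 0.67 ± 0.16 and 0.61 ± 0.17 and passed over the list alone, and Egr2 differed by −0.39 ± 0.13. Apoptosis regulators had a median of 0.10 over 17 members (0.311), with Fasl past the threshold over the list alone, and Cflar, Bcl2 and Cycs at 0.37 ± 0.14, 0.46 ± 0.19 and −0.26 ± 0.10. Cholesterol and fatty acid synthesis genes went both ways, with a median of 0.01, a mean of −0.07 and a downward test direction over 19 members (0.26). Sqle, Fasn, Fdps and Hmgcs1 differed by −0.40 ± 0.16, −0.30 ± 0.12, −0.50 ± 0.25 and −0.43 ± 0.26, and Hmgcs1 by −0.28 without isotype replicate 2 and −0.25 without anti-IL-10R replicate 4. Without isotype replicate 1 this list was lower at a camera adjusted p of 0.016, with an adjusted p = 0.42 with an estimated correlation.

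The spleens held leukaemic B cells, so markers of other cells that could remain in the sort were examined without a filter on dim genes. The B cell and CLL list was lower in the anti-IL-10R arrays, with a median change of −0.21 and 19 of 21 members lower (camera adjusted p 0.00404, adjusted p = 0.72 with an estimated correlation). No member passed over all genes or over the list alone. The MHC class II genes H2-Eb1 and H2-Ab1 differed by −0.38 ± 0.14 (SE) and −0.56 ± 0.23, Fcmr by −0.50 ± 0.19 (−0.32 without isotype replicate 3) and Siglecg by −0.38 ± 0.17 (−0.21 without isotype replicate 1). The list mean was 5.50 to 5.95 in the isotype and 5.37 to 5.58 in the anti-IL-10R arrays. It was lower in the group in which cell cycle, glycolysis, oxidative phosphorylation, heat shock and ribosomal protein genes were lower. The call ended without isotype replicate 3 (adjusted p 0.0813).

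The other 8 marker lists did not pass (camera adjusted p 0.805 for the erythroid list and 0.908 for the rest). Median changes were 0.02 for the monocyte and macrophage list (Ms4a6c 0.64 ± 0.33 SE, C1qa −0.26 ± 0.13, Lyz2 −0.48 ± 0.28, Mertk −0.29 ± 0.16) and 0.02 for neutrophils (Ly6g −0.51 ± 0.21, Ltf −0.35 ± 0.16). They were 0.03 for dendritic cells (Zbtb46 0.38 ± 0.15, Batf3 0.31 ± 0.14) and −0.06 for NK cells (Eomes, also expressed by effector CD8 T cells, 0.26 ± 0.11). They were 0.01 for CD4 and regulatory T cells, 0.10 for the erythroid list, near 0 (−0.003) for platelets and 0.04 for stroma and endothelium (Pecam1 0.69 ± 0.29). The means of the neutrophil and CD4 lists, both −0.05, had the opposite sign to their medians. Each of these medians except that of the erythroid list turned its sign when some single array was left out. That of the erythroid list spanned 0.02 (without isotype replicate 2) to 0.18 (without isotype replicate 1), and was 0.30 with the B cell covariate. Without isotype replicate 1 the differences were 0.33 for Ms4a6c, −0.18 for Lyz2 and Mertk, −0.28 for Ly6g and 0.36 for Pecam1, and that of C1qa was −0.16 without anti-IL-10R replicate 1. In the CD4 list, Ikzf2, which encodes Helios, differed by 0.69 ± 0.17 and passed over the list alone. Foxp3, the factor of regulatory T cells, was 6.25 ± 1.17 (SD, n = 4) and 5.33 ± 0.23, a difference of −0.92. Isotype replicate 1 had 7.97 and the other isotype arrays 5.46 to 5.95, and without it the difference was −0.35. In the erythroid list only Car2 passed over all genes. For platelets, Itgb3 differed by −0.39 ± 0.19.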

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

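The wording of the tests of isotype replicate 1, of isotype replicate 1 as the source of the cell cycle change, and of the B cell genes was chosen after those patterns had been seen. The tests of the number of changed genes and lists, of signal level and of the B cell covariate were set before.

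For each named gene and list mean, the highest and the lowest array of a group were compared with the nearest of the other 3, and 27 of 310 group values stood apart. Chance alone sets about 1 in 20 apart. Isotype replicate 1 held 11 of them. It was low for Dscam (7.47, nearest array 8.11), Cd44 (6.05, nearest 6.56), Pdcd1 (10.34, nearest 11.10) and Cd27 (9.999, nearest 10.37). It was also low for the means of 4 lists, inhibitory receptor and exhaustion (8.90), IL-10 receptor and STAT3 signalling (8.74), interferon gamma response and MHC class I (8.84) and glycolysis (8.15). It was high for Hspe1 (10.14), Siglecg (6.11) and Ly6g (5.10). In other isotype arrays, replicate 2 was high for Xcl1 (10.42), and replicate 4 was high for Il10ra (9.997, nearest 9.90), Il18r1 (7.08) and C1qa (5.97) and low in the platelet marker mean (5.18).

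Among the anti-IL-10R arrays, replicate 1 was high for Fam83d (7.37) and Hsp90aa1 (8.25) and low in the NK cell (5.39) and platelet (5.15) marker means. Replicate 2 was low for Cd3e (12.57, nearest 12.60) and high for Zbtb7b (6.46). Replicate 3 was high for Emb (6.47) and in the inhibitory receptor and exhaustion mean (9.77) and low for Hspe1 (9.11). Replicate 4 was high for Il7r (4.34, nearest 3.41, a dim gene) and low for Fdps (7.998).

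Isotype replicate 1 stood apart from the 7 other arrays over all genes. On the 500 genes that best part the groups without it, with 0 as the mean of the other isotype arrays and 1 as the anti-IL-10R mean, its median position was 0.40, against 0.75 to 1.00 for the anti-IL-10R arrays and 0.04 to 0.25 for the other isotype arrays, each left out and placed in the same way, which argues against an anti-IL-10R array under a wrong label. Of the 9 marker lists for other cells, 0 were higher in it than in both the other isotype arrays and random lists matched on level, but its neutrophil, NK and CD4 lists (excess 0.26, 0.24 and 0.19) lay above every other isotype array (at most 0.06, 0.13 and 0.12), and Foxp3 (7.97, others 5.46 to 5.95), Lyz2 (6.66, others 5.26 to 5.67) and Retnlg (4.23, others 3.18 to 3.44) were high. An admixture of such cells and a difference of the array itself cannot be told apart: random lists matched on level were higher in it by a median of 0.23 for neutrophils but 0.10 for NK and 0.04 for CD4, and the excesses stayed below the upper ends of the central 95% of such lists (0.46, 0.37 and 0.32). A narrower signal range may account for part of it, since the slope of its values on the mean of the other isotype arrays was 0.90, where the others had 0.98 to 1.00; what narrowed the range, such as a lower amount of RNA, and a biological difference of that sample stay open, as untested.

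Cell cycle genes were lower after IL-10R blockade, with a median change of −0.63. The tables argue against isotype replicate 1 as the source (−0.72 without it). It had the lowest list mean of its group (9.16, others 9.51 to 9.65), so leaving it out could only enlarge the fall of that mean. They also argue against a trend with signal level (the lowest of 10000 random lists matched on level had −0.17). Fewer dividing leukaemia cells in the sort are not excluded. With the B cell marker mean of each array as a covariate the median was −0.65 (camera adjusted p 3.47e-21 with the preset correlation, adjusted p = 0.63 with an estimated correlation, against 0.40 without the covariate). That mean may track such cells poorly, so the test cannot decide. Only 10 of its 21 members had a mean above the limit for dim genes, and the brightest, Ighm, was higher (0.35). Of the 35 ways to part the arrays into 4 and 4, only the real one gave as many changed genes (304, highest other 0). A share of 1 in 35 is the smallest that this test can give. The other splits mix the groups, so a group difference widens their spread, and chance is not excluded for the gene count. For the number of lists it cannot be excluded either. Of the 35 splits 2, the real one included, called 9 lists and the highest other reached 9. That other split set isotype replicate 1 with anti-IL-10R replicates 1, 2 and 3 against the remaining arrays. Most arrays of a group thus stayed together, so its count does not show what chance alone gives. Splits with 2 isotype arrays on each side called at most 3 lists. A lower share of dividing cells among PD-1hi effector CD8 T cells after IL-10R blockade is a hypothesis that these tests leave standing. A difference in which cells fell inside the sort windows, or in the time of processing, was not tested.

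B cell marker genes were lower in the anti-IL-10R arrays, by a median of 0.21 on the log2 scale (a change of −0.21). The sort excluded lineage-positive cells and required the T cell receptor, which would remove B cells; 10 of the 21 members had a mean above the limit for dim genes, and none is in another list. A candidate explanation is a lower admixture of B lineage cells, which would lower their abundant transcripts. The 5 brightest members had a median change of −0.41: H2-Ab1, H2-Eb1, Fcmr and Cd79b (−0.19 without isotype replicate 3) were lower by more than their SEs, but the brightest, Ighm, was not (0.35 ± 0.24 SE, mean level 10.06; 0.20 without isotype replicate 1 and 0.58 without isotype replicate 3). Ighm alone of these 5 members was higher, and signal levels of different genes do not rank their abundance. Admixture and a change within T cells therefore cannot be told apart.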

How the results depend on the processing

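No result turned its direction while past the threshold, and the alternatives were set before the data were examined, except the counts of list members without isotype replicate 1 and the tests of the added lists. The 304 genes kept their direction in every setting that tested them (241 of 241 under the stricter filter, 303 of 303 with the mean of all rows). Their groups did not overlap. The filters, variance model, array weights, Welch test, replicate block and leaving out 1 array could therefore not turn their direction. Their number moved widely. It was 145 without a filter on dim genes (67 higher, 78 lower), where more genes share the adjustment, and 460 with a stricter filter (239 higher), where fewer do. It was 631 after quantile normalization (427 lower), 526 after centring (307 lower), 1469 with array weights (654 higher, 815 lower), and 422 with a trended and robust variance (225 higher). It was 26 with the Welch test (17 higher, 9 lower), which pools no variance. With the B cell covariate it was 3 (2 higher, 1 lower). There the median size of the change of the 304 genes was 0.76, against 0.71 without it, while the median SE was 0.19 against 0.13, so the calls ended with larger errors and not with smaller changes as a whole. It was 896 at an adjusted p below 0.1 (476 higher, 420 lower), 52 with a 2-fold minimum (24 higher, 28 lower) and 12 over all rows without a filter (8 higher, 4 lower). The cause was not tested for normalization.

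With the replicate block the number was 4 (2 higher, 2 lower), with no change in the calls of lists. The labels do not say whether the numbers pair the arrays, but the sample titles of replicates 2 to 4 carry the same number in both groups. Deviations of same-numbered arrays from their group means correlated at −0.05, 0.12, 0.02 and −0.16. Of the 4 numbers, 1 had its best partner in its own number. Isotype replicate 1, which stood apart, enters the isotype mean and so the deviations of all isotype arrays. A pairing is therefore not excluded.

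With 1 array left out, 3 to 1112 genes passed (2 to 403 higher, 1 to 709 lower). Most passed without isotype replicate 1 and fewest without isotype replicate 4. With 1 array left out, 2 to 4 lists were higher and 4 to 6 lower. Camera adjusted p spanned 0.0108 to 0.0959 for IL-10 receptor and STAT3 signalling and 0.00409 to 0.108 for type I interferon. It spanned 0.00409 to 0.117 for ribosomal proteins and 0.000381 to 0.0813 for the B cell markers, where 0 to 1 marker lists passed. The other 6 lists stayed past the threshold, with p up to 2.79e-22 for cell cycle, 6.12e-07 for exhaustion, 0.00262 for glycolysis, 0.0249 for oxidative phosphorylation, 0.00465 for interferon gamma and 0.0216 for heat shock.

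With an estimated correlation 0 lists were higher and 0 lower (2 had an unadjusted p below 0.05). Adjusted p was 0.400 for cell cycle and exhaustion, 0.482 for the IL-10 receptor, both interferon lists, glycolysis and heat shock, and 0.562 for oxidative phosphorylation and ribosomal proteins. Of marker lists 0 passed (B cell 0.725). By fry 1 list was higher (exhaustion) and 1 lower (cell cycle). By fry the adjusted p was 0.0602 for the IL-10 receptor, 0.0882 for type I interferon and glycolysis, 0.0806 for interferon gamma and heat shock, 0.199 for oxidative phosphorylation and 0.206 for ribosomal proteins. With the B cell covariate 2 lists were higher, with p 0.0912 for the IL-10 receptor and 0.175 for type I interferon, and 0 marker lists passed (B cell 0.972), by construction. Under the alternatives that kept all arrays, the list medians spanned 0.02 to 0.18 for the IL-10 receptor, 0.10 to 0.35 for type I interferon, −0.22 to −0.13 for oxidative phosphorylation, −0.21 to −0.08 for ribosomal proteins and −0.28 to −0.09 for heat shock. Of the lists that did not pass, the costimulatory median was 0.18 without a filter, and the chemokine median 0.25 with the stricter filter. The other 6 spanned 0.02 to 0.10 (cytotoxic effector), −0.12 to 0.01 (progenitor), 0.04 to 0.13 (IL-2), −0.21 to 0.01 (cholesterol), −0.01 to 0.12 (immediate-early) and 0.03 to 0.16 (apoptosis). Of the added lists, ribosome biogenesis lost its call with an estimated correlation (0.0739). Of the 35 named genes past the threshold, 3 to 35 stayed past it when 1 array was left out and 26 to 35 under the filters, scalings, row rule, variance model and array weights. Signal over background was not measured, so dim genes are the least certain.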

Other observations

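The lists of this paragraph and the next were written after the table of changed genes had been seen, so their direction is not independent evidence; the histone test was also worded after its members had been seen. Genes of DNA and nucleotide production outside the cell cycle list were lower after IL-10R blockade. Of 16 measured replication-dependent histone genes, 13 were lower with a median change of −0.68 (−1.06 under the stricter filter on dim genes), 10 fell over all genes and 12 over the list alone, led by H1f1 (−2.12 ± 0.13 SE), H4c9 (−1.10 ± 0.14) and H2ac10 (−0.73 ± 0.11). These genes are near-identical copies, so single members are uncertain. Of 16 nucleotide synthesis genes, 15 were lower with a median of −0.45 and 4 fell over all genes. These were Shmt2 (−0.74 ± 0.14), which feeds one-carbon units into nucleotide synthesis, Ctps (−0.69 ± 0.13) and Cad (−0.67 ± 0.13) of pyrimidine synthesis, and Gart (−0.63 ± 0.13) of purine synthesis. Of 32 ribosome biogenesis genes, 31 were lower with a median of −0.30, but none passed over all genes or over the list alone; 9 passed over all genes without isotype replicate 1.

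Genes known as FOXO targets or as brakes on cell division were higher: 16 of 18 had a positive change, the median was 0.37, 2 rose over all genes and 7 over the list alone. The 2 were Sesn1 (0.66 ± 0.13 SE), a stress-induced inhibitor of mTORC1, and Tgfbr2 (0.51 ± 0.11), a receptor for TGF-beta; Ccng2 (0.55 ± 0.12) and Foxo3 (0.56 ± 0.18) passed over the list alone.

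The hypothesis that the lower cell cycle genes may be part of a wider fall of growth genes was tested with these 4 lists by camera, adjusted over the 4. Histone genes (8.81e-12 with the preset correlation, adjusted p = 0.00742 with an estimated correlation) and nucleotide synthesis genes (4.96e-09 and 0.028) were lower with both, and FOXO target and quiescence genes (2.16e-05 and 0.00742) were higher with both. Ribosome biogenesis genes were lower with the preset correlation (4.96e-09) and did not pass with an estimated one (0.0739). These values decide nothing about the hypothesis, because the lists were written after the changed genes had been seen; the histone list holds H1f1, H2bc12, H2bc18 and H2ac21, which are among the 12 named genes that fell most. It stays open for all 4 lists. The lists share the arrays and the groups of the cell cycle result, so they are not separate evidence for it.

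The single genes of this paragraph passed the threshold over all genes and were chosen after their values were seen; they stand for no group, and no list of their kind was tested. Mlxip, which senses glucose-derived metabolites, and Txnip differed by 0.80 ± 0.14 (SE) and 0.81 ± 0.11. The cytokine receptor genes Il17rb, which was dim in the isotype arrays (mean 4.98), and Il12rb1 were higher by 1.31 ± 0.22 and 0.64 ± 0.13, and Il18rap was lower (−0.95 ± 0.19). The signal transducer Stat4 and the cytokine gene Csf1 were higher by 0.51 ± 0.11 and 0.90 ± 0.10.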
